A study of Mus musculus with 40 samples.

How the data were processed

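Sorted basal, luminal and stromal cells of the mammary gland of ovariectomized FVB mice aged 8 weeks were profiled after 14 days of subcutaneous sesame oil, estradiol (E, 10 μg), progesterone (P, 1 mg) or both (EP). Per the labels, RNA was isolated with a PicoPure kit, copied and amplified by long-distance PCR (SMARTer), labelled with Cy5 by a ULS kit and hybridized against a universal mouse reference RNA in Cy3, with no dye swap. The design text calls the replicates biological; how many mice each holds, and the surface markers of the sort, are not given in the sources used here. The 40 arrays lie on 5 slides of 8.

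The deposited scanner files hold intensity values per spot and channel, the mean signal and the median local background, which per the file headers Agilent Feature Extraction 10.7.3.1 produced, together with processed signals detrended and dye-normalized by LOWESS. The deposited series values are log2 ratios of sample over reference normalized by the authors; the method is not given in the sources used here. Over arrays they correlated with the ratios computed here at r = 0.894 to 0.975, with slopes of 0.979 to 2.12 and column medians of -0.11 to 0.05.

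Raw signals were corrected with limma 3.58.1 in R 4.3.3 (version 1.17.8 of data.table): normexp background with an offset of 50 and loess within each array, giving log2 of Cy5 over Cy3. Flagged spots were left out and replicate spots averaged. Of 55681 probes 26425 could be given a symbol through the RefSeq names in the files (GRCm38.p6, names only; 20724 of 25085 RefSeq names matched, 20022 genes), and the others kept their own name and count as genes in all totals. Of the probes of 1 gene the brightest over all arrays was used. A gene was tested where its Cy5 signal was well above background, as called by the scanner software, on at least 3 arrays of the fit.

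limma (lmFit, eBayes) was run within each compartment for the hormone comparisons and departures from additivity (EP - E - P + vehicle), and over all 40 arrays for compartments and for differences of a hormone's effect between them; residual degrees of freedom were 10, 10, 8 and 28. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the comparison. 19 gene lists and 14 marker lists were tested with camera (preset correlation 0.01) in the 9 comparisons with vehicle, adjusted over all 297 tests. 59 tests were called, and 4 of them also with an estimated correlation (median 0.0947): mitosis in luminal E and EP and endothelial markers in basal E and EP. The lists were estrogen-responsive, progesterone-responsive, mitosis, DNA replication, milk and secretory, WNT and RSPO, EGF FGF IGF, chemokines, extracellular matrix, matrix proteases, fatty acid synthesis, cholesterol synthesis, interferon response, MHC class II, immediate early and dissociation stress, unfolded protein response, glycolysis, oxidative phosphorylation and ribosome biogenesis. The markers were of hormone-sensing luminal, luminal progenitor, pan-luminal, basal and myoepithelial, fibroblast, endothelial, pericyte, adipocyte, pan-leukocyte, macrophage, lymphocyte, erythrocyte, Schwann and skeletal muscle cells.

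Lists, limma and camera tests, alternatives and the rule for named genes were fixed before the data were examined. Named genes had a symbol, passed, and had no overlap between the arrays of both groups: the 12 highest and 12 lowest for EP against vehicle, 6 and 6 for E and P, 4 and 4 for EP against E or P, 10 and 10 between compartments (6 and 6 named for stroma), and the 4 largest of each difference or departure (overlap allowed). Not every gene this rule picks is named, and none with 1 array in a group. From each list up to 4 members with the smallest p were eligible. A panel of 25 genes (Esr1, Pgr, Greb1, Areg, Tnfsf11, Tnfrsf11a, Wnt4, Rspo1, Id4, Prlr, Elf5, Cxcl12, Cxcr4, Ccnd1, Mki67, Csn2, Krt5, Krt14, Krt8, Krt18, Epcam, Vim, Pdgfra, Pecam1 and Ptprc) was followed in every comparison; members that did not pass are given as a count and, unless dim (well above background on no array of a group compared), a range, and between compartments, and in stromal differences, some that passed are counted only. Where no array of the dimmer group was well above background, the fold is a lower bound, "at least", the smaller (a choice made after the values were seen) of the fold of the log2 ratios and of the bright group's mean sample signal (log2, after loess and Aquantile normalization) over the dim group's mean of the higher of its own signal and the array's lowest signal well above background; such folds are open to dye bias. They ignore sampling error. No fold is given where neither group was above background. Of 72 named values past the threshold with further probes, 3 had one of opposite sign.

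Alternatives were no background correction, the scanner's processed signals, scale normalization between arrays, the sample channel alone, no filter or a stricter one (well above background on 50% of the arrays), the mean of a gene's probes, slide as a fixed block, a block for replicate number, fits over other samples, array weights, the authors' log2 values, and each array left out. The scanner's signals moved the median of all genes by 0.16 and 0.23 in basal E and EP, 0.14 in EP against P, -0.15 in luminal additivity, 0.10 in stromal EP and -0.11, -0.22 and -0.11 in the E and EP differences luminal minus basal and EP stromal minus basal. The authors' values moved it by -0.27, -0.27, -0.29 and 0.29 in basal E, P, EP and additivity, 0.29, 0.15 and 0.25 in the E, P and EP differences luminal minus basal, and 0.25, 0.26 and 0.26 stromal minus basal. No filter moved it by -0.11 in basal EP against P, and leaving out the arrays in doubt by -0.11 in the P and EP differences stromal minus basal. Counts were also run without 4 arrays in doubt, a choice made after the data were seen: basal vehicle replicates 1 and 3, luminal P replicate 2 and luminal EP replicate 4. A second endothelial list was written after the first was examined. A split gives genes higher and lower. "Within slides" gives a list's median on slides holding both groups.

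On data simulated with the design and spread of each comparison, the test recovered 44.8, 80.6 and 97.0% of genes changed by 2-, 4- and 8-fold in luminal EP against vehicle, 20.9, 67.2 and 90.9% in basal EP and 35.8, 85.1 and 98.5% in stromal EP. No pair of arrays was identical (highest r 0.962 within a group). Replicate numbers did not pair arrays across groups: the mean correlation of residuals was 0.0113 over 56 same-numbered pairs of arrays of 1 compartment and -0.0186 over 38 pairs across compartments, so no paired test was used. limma's test for slide called 0 genes but leaves slide effects open. At an unadjusted p under 0.05 were 1831 of 20580 basal, 2243 of 19016 luminal and 1480 of 20384 stromal genes. Slide as a block lost 5 of 59 list calls and moved the lists' medians by -0.31 to 0.21. Array 2 of a group is its replicate 2.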

Results

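RNA of sorted mammary cells of adult female FVB mice was measured on 2-colour Agilent arrays. Ovariectomized mice had 14 days of vehicle, 17β-estradiol (E), progesterone (P) or both (EP). Basal and luminal epithelial cells gave 3 vehicle, 4 E, 3 P and 4 EP arrays each, and stromal cells 3 of each. In the Cy5 channel 34.9 to 52.1% of probes were well above background, with median signals from 115 to 854. Luminal EP replicate 4 had the lowest share. Basal vehicle replicates ranged from 35.3 to 49.1%, with median r in the group of 0.686 to 0.725 (others at least 0.814). The reference of luminal P replicate 2 was dim, its share 44.7% against at least 67.0% elsewhere. Values below are log2 fold changes ± their standard error, and the number of arrays limits their precision.

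The compartments differed in most genes that define them. Over all treatments (n = 14 luminal, 14 basal and 12 stromal arrays; 13 luminal for Ltf, Ehf, Krt8, Epcam and Greb1, 13 basal for Ehf and Tnfrsf11a, 11 stromal for Csn2), luminal cells exceeded basal cells in the antimicrobial protein Ltf, Fcgbp, haptoglobin (Hp), Bik, the adhesion proteins Ceacam2 and Cldn3, Cd82, the mucin Muc1 and the transcription factors Foxa1 and Ehf, at 5.33 ± 0.23, 5.77 ± 0.18, 5.09 ± 0.21, 4.44 ± 0.25, 3.66 ± 0.18, 3.50 ± 0.15, 3.65 ± 0.20, 3.43 ± 0.13, 3.48 ± 0.30 and 3.47 ± 0.17. Basal cells held more of the contractile genes Myl9, Cnn1, Acta2 and Myh11, at -5.00 ± 0.11, -4.28 ± 0.16, -4.02 ± 0.14 and -3.76 ± 0.13 luminal over basal, and of Sparc, the basement membrane collagens Col4a1 and Col4a2, Arc, Serpina3n and Vim, at -5.16 ± 0.14, -4.09 ± 0.11, -4.13 ± 0.13, -4.34 ± 0.16, -3.75 ± 0.13 and -3.74 ± 0.13. Luminal to basal, Esr1 and Pgr, the estrogen and progesterone receptors, lay at 1.66 ± 0.18 and 1.35 ± 0.11, and the alveolar regulator Elf5 was at least 9.49-fold higher. 13 of 24 panel genes were higher luminal to basal and 7 lower. The rest ran from -0.40 (Tnfrsf11a) to 0.23 (Krt8, a luminal marker). Its bearing on sort purity was not tested.

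Stromal cells were marked by collagens and other matrix genes. Against basal cells the genes Col3a1, Col1a2, Col1a1, Col6a2, Dpep1 and lipoprotein lipase (Lpl) lay at 5.72 ± 0.30, 5.56 ± 0.24, 5.40 ± 0.23, 5.16 ± 0.15, 4.99 ± 0.15 and 4.93 ± 0.27. The epithelial genes Chil1, Krt13, Lcn2, Itga6, Cnn1 and Krt14 were lower, at -6.17 ± 0.14, -6.01 ± 0.17, -5.75 ± 0.13, -5.47 ± 0.11, -4.92 ± 0.16 and -4.72 ± 0.15, and Plekhb1, Krt5 and Epcam, not well above background in stromal cells, were at least 42.2, 19.9 and 9.94 fold lower. Against luminal cells Col3a1, Col1a2, Col1a1, Sparc, Rarres2, Bgn and Vim were higher, at 6.87 ± 0.30, 6.74 ± 0.24, 6.35 ± 0.23, 6.27 ± 0.14, 5.82 ± 0.20, 5.74 ± 0.19 and 5.12 ± 0.14. Lower were Fcgbp, Ltf, Lcn2, Cd24a and Hp, at -5.94 ± 0.19, -5.86 ± 0.24, -5.68 ± 0.13, -5.39 ± 0.10 and -5.26 ± 0.21, with Ceacam2, Epcam and Elf5 at least 43.2, 14.4 and 8.92 fold lower. 5 of 24 panel genes were higher stromal to basal and 11 lower; the 7 others not dim ran from -0.44 (Csn2) to 0.12 (Prlr). 4 of 24 were higher stromal to luminal and 16 lower. The rest ran from -0.39 (Esr1) to 0.35 (Greb1). Of the genes set luminal to basal, well above background were Foxa1 on 1 of 14 basal arrays, Bik and Muc1 on 2, Ltf on 6, Pgr on 10, Cldn3 on 11, Esr1 on 12, Hp and Cd82 on 13; Ehf on 6 of 13 basal arrays; Serpina3n on 5 of 14 luminal arrays, Myh11 on 8, Col4a2 on 10, Col4a1 on 12, Arc on 13. Stromal to basal, well above background were Dpep1 and Lpl on 8 of 14 basal arrays, Col6a2 on 11; Chil1 on 1 of 12 stromal arrays, Krt13 on 5, Itga6 on 6, Cnn1 on 11. Stromal to luminal, well above background were Bgn on 8 of 14 luminal arrays, Rarres2 on 12, Col3a1 on 13; Ltf on 2 of 12 stromal arrays, Cd24a on 8, Fcgbp on 10.

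For pan-luminal, hormone-sensing and progenitor markers, luminal against basal, of 14, 10 and 12 measured genes 12, 8 and 8 were higher and 0 lower (12, 8 and 9 up and 0 down adjusted over the list alone), with medians of 1.40, 1.59 and 1.54. The basal and myoepithelial, extracellular matrix and glycolysis lists lay lower: of 15, 31 and 15 measured genes 0 were higher and 14, 24 and 13 lower (0 up and 15, 25 and 13 down adjusted over the list alone), with medians of -2.24, -1.19 and -0.59. Fibroblast and interferon response genes lay higher in stromal than basal cells: of 15 and 23 measured genes 15 and 22 were higher and 0 lower (15 and 22 up and 0 and 1 down adjusted over the list alone), with medians of 2.81 and 1.05. In the same comparison, for pericytes, leukocytes, macrophages, lymphocytes, Schwann cells and skeletal muscle of 7, 9, 6, 7, 6 and 4 measured genes 5, 0, 1, 2, 1 and 1 were higher and 0, 1, 0, 1, 4 and 1 lower (5, 0, 1, 2, 1 and 1 up and 1, 1, 0, 1, 4 and 1 down adjusted over the list alone), with medians of 1.09, -0.12, 0.07, 0.06, -0.77 and 0.21; the mean of the muscle markers was -0.25. limma called 4160 genes higher and 4628 lower in luminal than basal cells, 5467 and 4911 in stromal than basal, and 5713 and 5184 in stromal than luminal. With slide as a block 8280, 10374 and 11062 genes passed.

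In luminal cells EP raised the kallikrein proteases Klk1, Klk1b3, Klk1b22 and Klk1b24 against vehicle, with log2 fold changes of 4.64 ± 0.34, 4.92 ± 0.34, 4.10 ± 0.30 and 4.10 ± 0.38 (n = 4 and 3), and the secreted peroxidase Gpx3 and the calmodulin-binding peptide Pcp4, at 4.50 ± 0.38 and 4.20 ± 0.21. The protease Napsa, Pate6, tenascin Tnxb, Pnmt, defensin Defb1 and Klk1b8 were not well above background in vehicle and were at least 20.6, 16.7, 14.2, 13.1, 12.5 and 10.5 fold higher. Calcitonin (Calca), RANKL (Tnfsf11) and the WNT amplifier Rspo1 were at least 9.71, 5.17 and 5.36 fold higher, and the estrogen target Greb1 and chemokine receptor Cxcr4 changed by 2.35 ± 0.36 and 1.23 ± 0.28. Osteopontin (Spp1), the antimicrobial Reg3g, pleiotrophin (Ptn), Pla2g10, Tspan1, Pgm5, Speer4a and the RNA helicase Upf1 fell, at -2.90 ± 0.26, -2.98 ± 0.35, -2.81 ± 0.22, -3.18 ± 0.76, -2.60 ± 0.24, -2.56 ± 0.26, -2.85 ± 0.83 and -2.82 ± 0.61, as did Esr1 itself, at -1.55 ± 0.22. Vim and Upf1 stood apart, high, on EP array 4, without which they changed by 1.55 ± 0.26 and -3.06 ± 0.65. Uroplakin Upk3a, Olfr372 and the nuclear receptor Nr5a2 were at least 7.77, 7.92 and 7.82 fold lower.

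Genes of cell division rose together in EP-treated luminal cells, among them Ube2c, Ccnb2 and Birc5 of mitosis (3.03 ± 0.22, 2.48 ± 0.21 and 2.16 ± 0.15), Mki67 (1.94 ± 0.37), Uhrf1 and the helicase subunit Mcm5 of DNA replication (2.78 ± 0.24 and 2.54 ± 0.30). Of 29 and 28 measured mitosis and DNA replication genes, 22 and 20 rose and 0 fell (26 and 26 up and 0 down adjusted over the list alone). camera gave adjusted p = 4.76e-22 and 1.37e-21, or adjusted p = 0.0484 and 0.0997 with an estimated correlation, for medians of 1.94 and 1.20 (1.79 to 2.06 and 1.03 to 1.40 within slides). Basal keratins Krt14 and Krt17 rose by 2.62 ± 0.27 and 1.91 ± 0.35, Krt5 was at least 3.24-fold higher, and Vim rose by 1.84 ± 0.31. Of 13, 27 and 24 measured basal and myoepithelial markers, extracellular matrix and oxidative phosphorylation genes, 6, 9 and 3 rose and 1, 0 and 0 fell (9, 10 and 7 up and 1, 1 and 0 down adjusted over the list alone). With medians of 1.08, 0.69 and 0.34 (1.03 to 1.32, 0.13 to 1.12 and 0.43 to 0.49 within slides), camera gave adjusted p = 2.08e-04, 1.25e-04 and 4.30e-04, or adjusted p = 0.226, 0.536 and 0.226 with an estimated correlation. Matrix members included Col6a1, Col4a1 and Lama4, at 2.50 ± 0.26, 1.71 ± 0.23 and 1.66 ± 0.31, and respiratory chain members Uqcrc1 and Cox5b, at 1.28 ± 0.37 and 1.01 ± 0.28. Lists without a call still held members that changed: for estrogen-responsive, WNT and RSPO, and growth factor (EGF FGF IGF) genes, of 17, 14 and 17 measured genes 2, 2 and 0 rose and 2, 2 and 5 fell (3, 3 and 0 up and 2, 4 and 5 down adjusted over the list alone), with medians of -0.02, 0.11 and -0.23 and camera's adjusted p = 0.805, 0.809 and 0.0806; the estrogen-responsive mean was 0.04. Among them were Cited1, the Wnt inhibitor Sfrp2 and the receptor Fgfr1, at -1.56 ± 0.19, -1.33 ± 0.29 and -2.19 ± 0.26. limma called 1017 of 21053 genes higher and 950 lower. No call was made for 15 panel genes, the 12 not dim at -0.31 (Pgr) to 0.89 (Wnt4). Measured on part of the arrays were Pgm5 and Sfrp2 on 1 of 4 EP arrays, Reg3g on 2, Speer4a on 3; Klk1b24, Greb1, Mcm5, Krt17, Col4a1 and Lama4 on 1 of 3 vehicle arrays, Klk1, Klk1b3, Klk1b22, Pcp4, Cxcr4, Ube2c, Ccnb2 and Mki67 on 2. 1471 genes passed with slide as a block (41 of 47 named) and 2895 without the arrays in doubt. It became 1060 and 1231 without vehicle arrays 2 and 3, and 1217 without EP array 2.

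**Figure D1:**
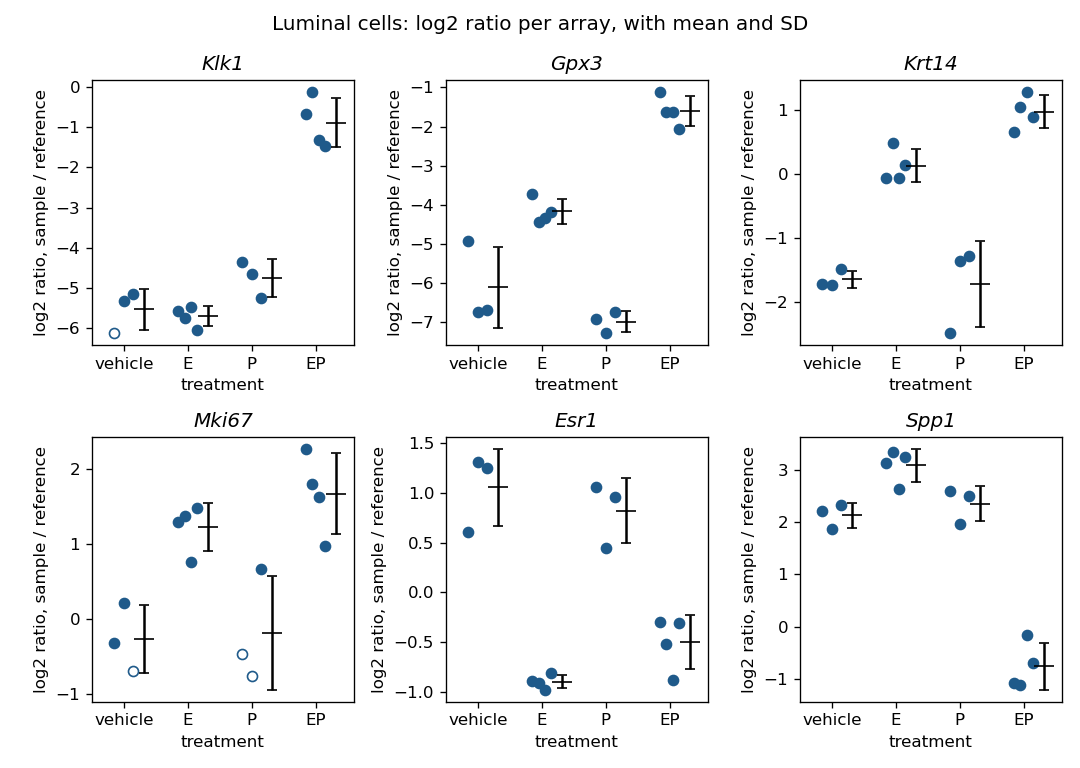
Log2 ratio of sample over reference on each luminal array (points, open where not well above background) with mean and standard deviation (bars) for 6 genes under vehicle, E, P and EP, n = 3, 4, 3 and 4.

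E alone, set against vehicle, changed fewer luminal genes. Amine oxidase Aoc1 and the secretoglobin Scgb3a1 rose by 3.73 ± 0.48 and 3.14 ± 0.25 (n = 4 and 3), and Pate11, the salivary mucin Smgc, Prol1 and Bbox1, an enzyme of carnitine synthesis, were at least 7.99, 6.14, 6.89 and 6.19 fold higher. The sodium pump regulator Fxyd2, Upk3a and Cfap126 fell, at -3.03 ± 0.19, -2.50 ± 0.30 and -2.09 ± 0.24, and Lipc, the channel Kcnh1 and Rgs5 were at least 4.67, 4.60 and 4.21 fold lower. Division genes rose again, with Ube2c, Ccnb2, Mcm5 and Mki67 at 2.25 ± 0.22, 1.90 ± 0.21, 2.02 ± 0.30 and 1.50 ± 0.37. Of 29 and 28 measured mitosis and DNA replication genes, 18 and 11 rose and 0 fell (23 and 17 up and 1 and 0 down adjusted over the list alone). The medians were 1.15 and 0.66, and 0.93 to 1.69 and 0.61 to 0.84 within slides (camera, adjusted p = 3.81e-20 and 3.87e-15, or adjusted p = 0.0484 and 0.200 with an estimated correlation). Krt14, Krt17 and Vim rose by 1.78 ± 0.27, 1.80 ± 0.35 and 1.33 ± 0.31 and Krt5 was at least 4.19-fold higher. Of 13, 27 and 20 measured basal and myoepithelial markers, extracellular matrix and fatty acid synthesis genes, 3, 3 and 4 rose and 0, 0 and 1 fell (8, 9 and 4 up and 0, 1 and 1 down adjusted over the list alone). camera gave adjusted p = 4.57e-05, 1.21e-04 and 0.0255, or adjusted p = 0.200, 0.536 and 0.395 with an estimated correlation, for medians of 0.78, 0.53 and 0.15 (0.37 to 1.23, 0.32 to 0.70 and 0.11 to 0.36 within slides). The basal genes Cnn1 and Myl9 stood apart, high, on E array 2, without which the basal list's median was 0.70, still called. The hormone-sensing markers Esr1, Tbx3 and Cited1 fell, at -1.95 ± 0.22, -1.50 ± 0.23 and -1.14 ± 0.19, as did H2-DMa and H2-DMb1 of antigen presentation, at -0.95 ± 0.21 and -0.97 ± 0.18. Of 10, 7, 8 and 5 measured hormone-sensing, MHC class II, endothelial and erythrocyte genes, 0 rose and 3, 2, 0 and 2 fell (0 up and 3, 2, 4 and 3 down adjusted over the list alone). With medians of -0.28, -0.57, -0.81 and -0.72 (-0.36 to -0.25, -1.14 to -0.50, -0.88 to -0.27 and -1.75 to -0.44 within slides), camera gave adjusted p = 0.00863, 0.00863, 9.34e-04 and 0.0391, or adjusted p = 0.376, 0.411, 0.376 and 0.376 with an estimated correlation.

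Further lists were called higher under E in luminal cells. Of 22, 22, 22, 20 and 15 measured milk and secretory, chemokine, cholesterol synthesis, unfolded protein response and glycolysis genes, 0, 0, 0, 0 and 1 rose and 0 fell (0, 0, 0, 1 and 2 up and 0 down adjusted over the list alone). The medians were 0.41, 0.40, 0.31, 0.33 and 0.21, and 0.24 to 0.43, 0.31 to 0.60, 0.09 to 0.43, 0.26 to 0.41 and 0.10 to 0.32 within slides (camera, adjusted p = 0.0148, 0.0268, 0.00444, 0.00424 and 0.0208, or adjusted p = 0.602, 0.376, 0.382, 0.444 and 0.532 with an estimated correlation). limma called 309 genes higher and 250 lower. Not passing were 19 panel genes, the 15 not dim at -0.85 (Pecam1) to 0.93 (Cxcr4). Above background on part of the arrays were Upk3a on 1 of 4 E arrays; Aoc1, Mcm5 and Krt17 on 1 of 3 vehicle arrays, Ube2c, Ccnb2 and Mki67 on 2. A block for slide left 429 genes (23 of 25 named), and leaving out the arrays in doubt 758. Without single arrays it was 207 and 242 without vehicle arrays 2 and 3, and 278 and 264 without E arrays 2 and 4.

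P alone changed 1 luminal gene: Fxyd2 fell by 1.66 ± 0.20 against vehicle (n = 3 and 3, for Greb1 2 and 3; limma, 1325 genes at an unadjusted p under 0.05). On simulated data of this comparison the test found 89.6% of genes changed by 4-fold. Of 20, 18 and 27 measured fatty acid synthesis, progesterone-responsive and extracellular matrix genes, 0 rose and 0 fell (0, 1 and 0 up and 0 down adjusted over the list alone). camera gave adjusted p = 0.00786, 0.0336 and 0.0427, or adjusted p = 0.376, 0.725 and 0.785 with an estimated correlation, for medians of 0.21, 0.05 and 0.20 (0.27, -0.04 and 0.09 within 1 slide). The calls of these lists ended with slide as a block (adjusted p = 0.0723, 0.0970 and 0.909). 24 panel genes did not pass, the 19 not dim at -0.48 (Pgr) to 1.19 (Cxcr4). The count was 0 with slide as a block (0 of 1 named) and 0 without the arrays in doubt, and the split 11 and 2 with the scanner's signals, 1 and 2 with the authors' log2 values and 9 and 6 with the sample channel alone. It was 20 and 0 without vehicle arrays 1 and 2, 0 without E array 3, 0, 0 and 0 without P arrays 1 to 3, and 0, 0, 0 and 2 without EP arrays 1 to 4.

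Adding P to E in luminal cells, EP set against E, raised the same kallikreins Klk1 and Klk1b3, by 4.81 ± 0.31 and 4.80 ± 0.32 (n = 4 and 4), and Napsa, Tnxb and Tnfsf11, at least 20.8, 13.5 and 4.11 fold higher. Greb1 and Rspo1 rose by 2.37 ± 0.33 and 1.85 ± 0.36. Spp1, the lipocalin Apod, Scgb3a1 and Aoc1 fell, at -3.85 ± 0.24, -3.21 ± 0.53, -2.90 ± 0.24 and -2.84 ± 0.44. limma called 215 genes higher and 265 lower. The 21 other panel genes did not pass, the 19 not dim at -0.38 (Tnfrsf11a) to 1.11 (Wnt4). Well above background were Rspo1 on 1 of 4 E arrays, Klk1b3 on 3. Blocking for slide left 363 genes (11 of 11 named), and 543 without the arrays in doubt, and the split 223 and 442 with the scanner's signals and 174 and 337 with the authors' log2 values. Leaving out single arrays gave 259 and 286 without E arrays 2 and 4, and 277 and 268 without EP arrays 1 and 2.

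Adding E to P, EP set against P, raised Gpx3, Klk1b3 and Klk1b22 by 5.38 ± 0.38, 4.63 ± 0.34 and 3.92 ± 0.30 (n = 4 and 3, for Greb1 4 and 2), with Klk1b24 at least 18.0-fold higher. Krt14, Greb1, Mki67 and Vim rose by 2.69 ± 0.27, 2.06 ± 0.40, 1.86 ± 0.37 and 1.26 ± 0.31 and Krt5 was at least 2.41-fold higher. Spp1, Pla2g10, Ptn and Esr1 fell, at -3.12 ± 0.26, -2.83 ± 0.76, -2.74 ± 0.22 and -1.32 ± 0.22, and Upk3a was at least 6.12-fold lower. limma called 708 genes higher and 716 lower. No call was made for 18 panel genes, the 15 not dim at -0.66 (Pecam1) to 1.22 (Rspo1). Measured on part of the arrays were Mki67 on 1 of 3 P arrays, Klk1b3 and Klk1b22 on 2. 136 genes passed with slide as a block (9 of 14 named) and 1639 without the arrays in doubt, and the split 879 and 1481 with the scanner's signals and 812 and 449 with scale normalization. It became 772 without P array 1, and 906, 783 and 2403 without EP arrays 1, 2 and 4. The EP effect exceeded the sum of the E and P effects for Klk1b3, Klk1 and Napsa, by 4.51 ± 0.49, 4.03 ± 0.48 and 3.68 ± 0.37, and lay below it for Spp1, by -4.07 ± 0.37. In all 29 luminal genes lay above and 25 below additivity (limma, 1548 at an unadjusted p under 0.05). Napsa was not well above background in at least 1 group. None of 24 panel genes passed, the 18 not dim with values from -0.89 (Cxcr4) to 2.09 (Greb1). A block for slide left 8 genes (2 of 4 named), and leaving out the arrays in doubt 56 higher and 51 lower, and the split 44 and 76 with the scanner's signals and 28 and 38 with the authors' log2 values. Without single arrays it was 35 without vehicle array 3, 31 without E array 2, 32, 91 and 35 without P arrays 1 to 3, and 33 and 90 without EP arrays 2 and 4.

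In basal cells, EP against vehicle raised Capn6, Phyhip, claudin Cldn10, the collagen-modifying enzyme Plod2, keratin Krt15 and the desaturase Scd1 by 3.65 ± 0.55, 3.32 ± 0.58, 3.30 ± 0.24, 3.09 ± 0.63, 3.09 ± 0.85 and 3.04 ± 0.47 (n = 4 and 3, for Phyhip 4 and 2). Arvcf, the oxysterol hydroxylase Cyp7b1, Them5, the kinetochore protein Kntc1, Dmrta1 and Zfp810 were at least 7.29, 9.60, 9.91, 7.30, 8.86 and 6.74 fold higher. Genes that fell included the chemokines Ccl21a and Ccl21b, neuropeptide Npy, Fabp4 and Plvap of fenestrated endothelium, at -4.01 ± 0.61, -4.21 ± 0.64, -4.19 ± 0.30, -3.76 ± 0.41 and -3.53 ± 0.49. Fam167b, the receptors S1pr1 and Adgrl4, the endothelial cadherin Cdh5 and Adamtsl1 were at least 12.4, 12.4, 10.8, 11.2 and 8.03 fold lower. Cxcr4 rose by 1.44 ± 0.25, its ligand Cxcl12 changed by -2.58 ± 0.26, and Vim, Krt18 and Epcam by -1.35 ± 0.24, -0.95 ± 0.21 and -1.13 ± 0.29.

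Endothelial markers fell together in the basal sort. Of 13 measured endothelial markers, 0 rose and 12 fell (0 up and 13 down adjusted over the list alone). With a median of -2.65 (-2.71 to -1.70 within slides), camera gave adjusted p = 1.90e-13, or adjusted p = 0.0484 with an estimated correlation. Egfl7 fell by 2.88 ± 0.25, and Pecam1 was at least 8.40-fold lower. Median log2 ratios of the list ranged from -0.77 to 0.16 on the 3 basal vehicle arrays, from -2.97 to -2.52 on the 4 basal EP arrays and from -3.22 to -1.68 on the 14 luminal arrays. Some division genes rose, with Mki67 and Ccna2 at least 5.19 and 4.38 fold higher and the helicase subunit Mcm7 and topoisomerase Top2a at 1.90 ± 0.51 and 1.82 ± 0.40. Of 27, 27 and 20 measured mitosis, DNA replication and fatty acid synthesis genes, 10, 2 and 5 rose and 0, 0 and 1 fell (14, 3 and 6 up and 0, 0 and 1 down adjusted over the list alone). The medians were 0.86, 0.57 and 0.50, and 0.79 to 0.94, 0.57 to 0.84 and 0.32 to 0.79 within slides (camera, adjusted p = 6.96e-07, 1.25e-04 and 0.0128, or adjusted p = 0.226, 0.226 and 0.376 with an estimated correlation). The desaturases Fads1 and Scd2 rose by 1.76 ± 0.35 and 1.49 ± 0.32, as did the interferon-induced Ifit3 and Isg15, by 1.51 ± 0.37 and 1.42 ± 0.34. Of 23, 24 and 20 measured interferon response, oxidative phosphorylation and ribosome biogenesis genes, 2, 2 and 0 rose and 0, 0 and 2 fell (2, 8 and 0 up and 0, 1 and 3 down adjusted over the list alone). camera gave adjusted p = 0.00241, 0.0119 and 0.0115, or adjusted p = 0.376, 0.444 and 0.376 with an estimated correlation, for medians of 0.59, 0.36 and -0.37 (0.21 to 0.95, -0.01 to 0.44 and -0.67 to -0.36 within slides). limma called 1007 of 22101 genes higher and 1068 lower. Not passing were 16 panel genes, the 12 not dim at -0.57 (Krt14) to 1.60 (Ccnd1). Above background on part of the arrays were Ccl21a on 1 of 4 EP arrays, Ccl21b and Plvap on 2, Npy on 3; Capn6, Plod2, Krt15, Scd1, Cxcr4, Top2a and Ifit3 on 1 of 3 vehicle arrays, Cldn10, Mcm7 and Fads1 on 2; Phyhip on 1 of 2 vehicle arrays. The count was 1108 with slide as a block (31 of 37 named), and the split 1509 and 756 with the scanner's signals. It was 4509 without vehicle array 2, and 962, 794, 828 and 876 without EP arrays 1 to 4. limma's array weights left 63 higher and 44 lower.

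**Figure D2:**
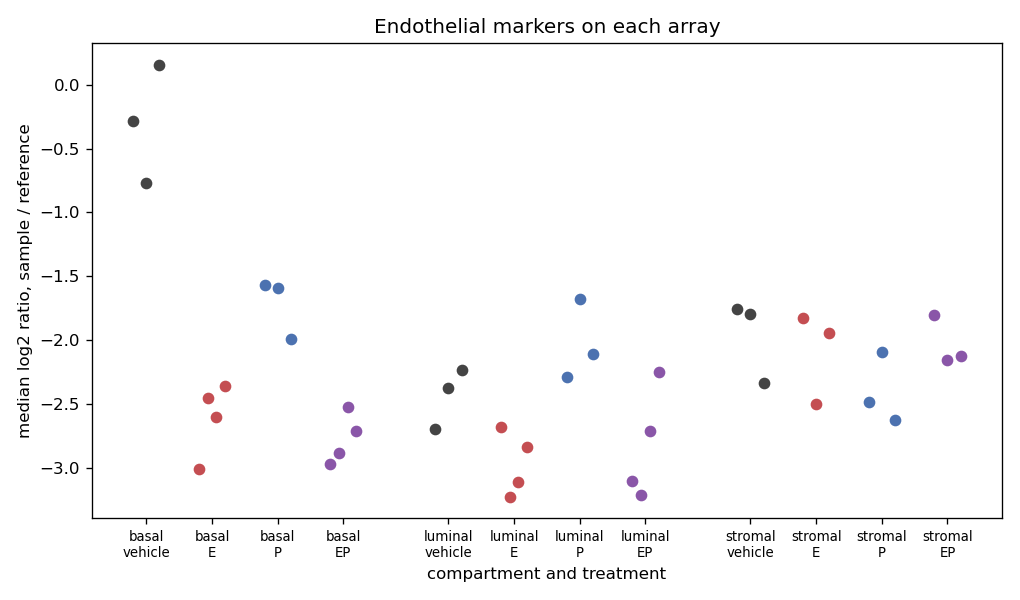
Median log2 ratio of the measured endothelial markers on each of the 40 arrays, by compartment and treatment. The basal vehicle arrays lie above all others.

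E alone in basal cells raised Cldn10 and Plod2 by 3.49 ± 0.24 and 3.02 ± 0.63 against vehicle (n = 4 and 3), and Hamp, the iron hormone hepcidin, Them5, the oncogene Mycn and Arvcf were at least 10.0, 9.44, 8.73 and 7.67 fold higher. RANKL (Tnfsf11) and Mki67 were at least 3.99 and 3.80 fold higher. Fabp4, Ctla2a and Ly6c1 fell, at -3.93 ± 0.41, -3.70 ± 0.58 and -3.46 ± 0.36, and Adgrl4 and P-selectin (Selp) were at least 10.5 and 11.0 fold lower. Cxcl12 and Pecam1 changed by -1.21 ± 0.26 and -2.85 ± 0.51. Of 13 measured endothelial markers, 0 rose and 10 fell (0 up and 13 down adjusted over the list alone). With a median of -2.51 (-2.55 to -1.69 within slides), camera gave adjusted p = 3.13e-15, or adjusted p = 0.0484 with an estimated correlation. Of 27, 27, 30 and 24 measured mitosis, DNA replication, extracellular matrix and oxidative phosphorylation genes, 3, 0, 2 and 0 rose and 0 fell (11, 0, 6 and 0 up and 0, 0, 1 and 0 down adjusted over the list alone). The medians were 0.67, 0.42, 0.32 and 0.33, and 0.27 to 0.89, 0.32 to 0.39, 0.11 to 0.41 and 0.14 to 0.53 within slides (camera, adjusted p = 9.28e-05, 0.00444, 0.0115 and 0.00272, or adjusted p = 0.376, 0.376, 0.495 and 0.376 with an estimated correlation). The matrix genes Col5a1 and Tnc rose by 1.44 ± 0.29 and 1.25 ± 0.31. limma called 395 genes higher and 511 lower. 19 panel genes did not pass, the 14 not dim at -0.69 (Epcam) to 1.77 (Ccnd1). Well above background were Pecam1 on 2 of 4 E arrays, Ctla2a on 3; Plod2 and Tnc on 1 of 3 vehicle arrays, Cldn10 and Col5a1 on 2. Blocking for slide left 426 genes (13 of 17 named), and the split was 694 and 405 with the scanner's signals. Leaving out single arrays gave 3480 and 559 without vehicle arrays 2 and 3, 406, 602, 370 and 418 without E arrays 1 to 4, and 559, 551, 528 and 524 without EP arrays 1 to 4. limma's array weights left 16.

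Under P alone in basal cells, Cox6b2 and the zinc finger gene Zfp780b rose by 2.47 ± 0.35 and 2.39 ± 0.48 against vehicle (n = 3 and 3, for Olfr578 2 and 3), and Olfr578, osteocalcin-related Bglap2, Hps3 and Nipal4 were at least 7.44, 6.46, 5.83 and 5.59 fold higher. Klra9 and Krtap5-4 fell, at -3.04 ± 0.61 and -2.65 ± 0.50, and Xlr4a, whose other probe had the opposite sign, and Ccny were at least 7.30 and 6.57 fold lower. Of 13, 20 and 15 measured endothelial, immediate early and fibroblast genes, 0 rose and 0 fell (0 up and 10, 1 and 0 down adjusted over the list alone). camera gave adjusted p = 1.53e-07, 0.00768 and 0.0115, or adjusted p = 0.179, 0.703 and 0.376 with an estimated correlation, for medians of -1.21, -0.47 and 0.50 (-2.04 to -1.58, -0.52 to -0.42 and 0.10 to 0.82 within slides). limma called 74 genes higher and 37 lower. The 23 other panel genes did not pass, the 17 not dim at -2.01 (Pecam1) to 1.39 (Ccnd1). Measured on part of the arrays were Klra9 and Krtap5-4 on 1 of 3 P arrays; Zfp780b on 1 of 3 vehicle arrays, Cox6b2 on 2. 48 genes passed with slide as a block (5 of 10 named), and the split was 153 and 40 with the scanner's signals and 56 and 52 with the authors' log2 values. It became 228 and 2620 without vehicle arrays 1 and 2, and 60, 61, 56 and 60 without EP arrays 1 to 4. limma's array weights left 0.

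EP set against E in basal cells differed in 32 genes, 4 higher and 28 lower. Cxcr4 rose by 1.52 ± 0.23 (n = 4 and 4), and Calca and Pate6 were at least 3.93 and 2.80 fold higher; the other had no symbol. Clusterin (Clu), the protease inhibitors Serpina1c and Serpina1e and Cxcl12 fell, at -2.66 ± 0.35, -2.51 ± 0.36, -2.55 ± 0.35 and -1.37 ± 0.24, and Ccn5 and Tnfsf11 were at least 5.91 and 3.42 fold lower. No call was made for 20 panel genes, the 17 not dim at -0.98 (Vim) to 1.38 (Rspo1). Above background on part of the arrays were Cxcr4 on 1 of 4 E arrays; Serpina1c and Serpina1e on 1 of 4 EP arrays. A block for slide left 1 gene (0 of 9 named), and leaving out the arrays in doubt 112, and the split 2 and 4 with the authors' log2 values. Without single arrays it was 50 without vehicle array 3, 14, 3 and 0 without E arrays 1 to 3, 19 without P array 2, and 0, 8, 0 and 10 without EP arrays 1 to 4.

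EP set against P raised Ltbp1, which binds latent TGF-beta, by 3.07 ± 0.38 (n = 4 and 3, for Olfr578 4 and 2), with Dmrta1, Opcml and the mitotic genes Bub1b and Mki67 at least 7.39, 6.75, 5.78 and 4.29 fold higher. Rprl2, Npy, Fabp4, Cxcl12 and Vim fell, at -3.40 ± 0.41, -3.14 ± 0.30, -2.54 ± 0.41, -1.82 ± 0.26 and -1.03 ± 0.24, and Olfr578 was at least 7.23-fold lower. limma called 179 genes higher and 262 lower. Not passing were 20 panel genes, the 15 not dim at -0.75 (Krt18) to 1.26 (Greb1). Well above background was Npy on 3 of 4 EP arrays. The count was 120 with slide as a block (10 of 11 named) and 2166 without the arrays in doubt, and the split 224 and 137 with the scanner's signals, 39 and 35 with the authors' log2 values and 210 and 175 with the sample channel alone. It was 897, 823 and 1197 without vehicle arrays 1 to 3, 289 without E array 4, 166 and 179 without P arrays 1 and 2, and 126, 72, 96 and 63 without EP arrays 1 to 4. The EP effect lay below the sum of the E and P effects for Il33, Olfr578, Gas2l3 and Nipal4, by -3.36 ± 0.51, -3.28 ± 0.44, -3.21 ± 0.42 and -3.05 ± 0.31; the other probe of Gas2l3 had the opposite sign. The 1 gene above it, Xlr4a, is named after its values were seen. In all 1 basal gene lay above and 6 below additivity (limma, 2374 at an unadjusted p under 0.05). Gas2l3, Il33, Nipal4 and Olfr578 were not well above background in at least 1 group. None of 23 panel genes passed, the 15 not dim with values from -1.57 (Ccnd1) to 1.08 (Cxcr4). Blocking for slide left 0 genes (0 of 4 named), and the split was 17 and 47 with the scanner's signals, 4 and 7 with the authors' log2 values, 0 and 2 with scale normalization, 0 and 3 with no background correction and 11 and 25 with the sample channel alone. Leaving out single arrays gave 37, 919 and 16 without vehicle arrays 1 to 3, 2, 2, 2 and 2 without E arrays 1 to 4, 1, 13 and 11 without P arrays 1 to 3, and 1, 1, 1 and 1 without EP arrays 1 to 4.

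In stromal cells, EP against vehicle raised the protease inhibitor Ctla2a, Gpx3, Rab4b, the respiratory chain subunit Ndufa6, the neurotrophin receptor Ngfr, Bsg and Rex1bd, by 4.55 ± 0.22, 2.90 ± 0.31, 3.01 ± 0.35, 2.90 ± 0.18, 2.85 ± 0.31, 2.81 ± 0.53 and 2.79 ± 0.30 (n = 3 and 3). Nop53, Alkbh6, interferon beta (Ifnb1), Krt23 and Akr1cl were at least 18.2, 8.39, 9.65, 9.51 and 5.42 fold higher. Hes2, Dhdh, Gucy2e and cytidine deaminase (Cda) fell, at -2.98 ± 0.40, -1.94 ± 0.40, -1.94 ± 0.38 and -1.90 ± 0.24. The WNT receptor Lgr5, Ftcd, Cox8b, Vnn1, Nup210l, Alkal2 and Gsdmcl-ps were at least 4.13, 5.27, 4.48, 3.84, 3.56, 3.94 and 2.97 fold lower. The estrogen targets Greb1 and Pgr and the WNT amplifier Rspo1 moved as well, Greb1 by 2.12 ± 0.28 and Pgr and Rspo1 at least 3.75 and 2.66 fold higher, while Esr1 and Pecam1 changed by -1.61 ± 0.30 and -1.30 ± 0.27.

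Some unfolded protein response and matrix genes rose in EP-treated stroma, among them the endoplasmic reticulum proteins Sdf2l1 and Manf by 2.09 ± 0.23 and 1.89 ± 0.28. The collagen cross-linker Loxl1, fibronectin (Fn1), Sparc and Col1a1 rose by 1.86 ± 0.24, 1.22 ± 0.19, 1.11 ± 0.14 and 1.03 ± 0.21. With the sample channel alone Sparc turned, at -0.31 ± 0.26. Of 20, 31, 15 and 23 measured unfolded protein response, extracellular matrix, fibroblast and interferon response genes, 10, 7, 4 and 4 rose and 0 fell (11, 10, 6 and 4 up and 0 down adjusted over the list alone). With medians of 0.71, 0.39, 0.39 and 0.27 (0.74, 0.62, 0.64 and 0.42 within 1 slide), camera gave adjusted p = 6.07e-08, 8.14e-05, 4.70e-04 and 0.00232, or adjusted p = 0.376, 0.660, 0.614 and 0.614 with an estimated correlation. Irf7 and Psmb8 led the interferon list, at 2.44 ± 0.38 and 1.55 ± 0.19. DNA replication, ribosome biogenesis and adipocyte genes lay lower, with Mcm7, Npm1 and Plin4 at -1.14 ± 0.28, -0.97 ± 0.15 and -1.38 ± 0.24. Of 23, 20 and 9 measured genes of these lists, 0 rose and 4, 4 and 3 fell (1, 0 and 0 up and 7, 6 and 3 down adjusted over the list alone). The medians were -0.37, -0.36 and -0.40, and -0.34, -0.39 and -0.72 within 1 slide (camera, adjusted p = 0.0349, 0.00131 and 0.0237, or adjusted p = 0.344, 0.344 and 0.344 with an estimated correlation). The DNA replication call ended with slide as a block (adjusted p = 0.103). For matrix proteases, where the collagenase Mmp13 was at least 2.22-fold higher, of 23 measured genes 1 rose and 0 fell (1 up and 0 down adjusted over the list alone), with medians of 0.25 and camera's adjusted p = 0.0637. limma called 964 of 21439 genes higher and 793 lower. 11 panel genes did not pass, the 9 not dim at -0.59 (Id4) to 0.65 (Vim). Measured on part of the arrays were Hes2 and Gucy2e on 1 of 3 EP arrays, Dhdh, Cda and Pecam1 on 2; Gucy2e on 1 of 3 vehicle arrays, Ngfr, Rex1bd, Greb1, Sdf2l1 and Irf7 on 2. 114 genes passed with slide as a block (15 of 40 named), and the split 1178 and 564 with the scanner's signals and 1254 and 1680 with the authors' log2 values. It became 877 and 720 without vehicle arrays 2 and 3, and 519, 539 and 1065 without EP arrays 1 to 3.

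E alone in stromal cells raised Ctla2a, Ndufa6 and Ngfr by 3.35 ± 0.22, 2.99 ± 0.18 and 2.94 ± 0.31 against vehicle (n = 3 and 3), with Alkbh6, Nop53 and Akr1cl at least 7.87, 13.4 and 6.57 fold higher. Hes2, the lipid receptor Lpar3 and Zfp395 fell, at -2.48 ± 0.40, -2.46 ± 0.67 and -2.42 ± 0.44, and Vnn1 and Alkal2 were at least 6.58 and 4.15 fold lower. Greb1 rose by 1.29 ± 0.28, and Pgr and Rspo1 were at least 2.26 and 2.46 fold higher. Esr1 and Pecam1 changed by -1.86 ± 0.30 and -1.12 ± 0.27 and the prolactin receptor Prlr was at least 1.90-fold lower. Sdf2l1, Manf, Loxl1 and Col1a1 rose by 2.09 ± 0.23, 1.84 ± 0.28, 1.72 ± 0.24 and 1.01 ± 0.21, and the immediate early gene Ier2 by 1.75 ± 0.39. Of 20, 31, 15 and 21 measured unfolded protein response, extracellular matrix, fibroblast, and immediate early genes, 7, 7, 5 and 1 rose and 0 fell (12, 10, 8 and 1 up and 0 down adjusted over the list alone). camera gave adjusted p = 3.87e-07, 4.57e-05, 1.19e-04 and 0.0384, or adjusted p = 0.405, 0.641, 0.602 and 0.802 with an estimated correlation, for medians of 0.68, 0.43, 0.60 and 0.32 (0.53, 0.13, 0.16 and 0.06 within 1 slide). The sterol genes Idi1 and Stard4 and the nucleolar Nop58 fell, at -0.85 ± 0.20, -1.20 ± 0.15 and -0.57 ± 0.15. Of 22, 20 and 5 measured cholesterol synthesis, ribosome biogenesis and erythrocyte genes, 0 rose and 2, 2 and 2 fell (0 up and 2, 7 and 2 down adjusted over the list alone). With medians of -0.49, -0.27 and -0.96 (-0.61, -0.30 and -0.82 within 1 slide), camera gave adjusted p = 3.90e-04, 0.00930 and 0.0337, or adjusted p = 0.376, 0.376 and 0.506 with an estimated correlation. The erythrocyte markers call ended with slide as a block (adjusted p = 0.123). limma called 806 genes higher and 811 lower. The 10 other panel genes did not pass, the 8 not dim at -0.75 (Krt14) to 0.56 (Vim). Above background on part of the arrays were Lpar3 on 1 of 3 E arrays, Hes2 and Zfp395 on 2; Ngfr, Greb1, Sdf2l1 and Ier2 on 2 of 3 vehicle arrays. A block for slide left 26 genes (4 of 25 named), and the split 992 and 621 with the scanner's signals. Without single arrays it was 640 and 506 without vehicle arrays 2 and 3, and 1068, 848 and 551 without E arrays 1 to 3.

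P alone in stromal cells raised Ndufa6, Rex1bd and the adaptor subunit Ap2s1 by 2.73 ± 0.18, 2.64 ± 0.30 and 2.31 ± 0.26 (n = 3 and 3), with Exosc4, Ctnna2 and Adamts10 at least 5.39, 4.73 and 4.57 fold higher. Serpina1d, Nbea and Pecam1 fell, at -2.08 ± 0.38, -1.97 ± 0.16 and -1.48 ± 0.27, and the lectins Clec4g and Clec1a, coagulation factor F8 and Abca13 were at least 3.70, 3.35, 3.18 and 3.21 fold lower. Ier2 rose by 2.12 ± 0.39. Of 21, 31, 20 and 15 measured immediate early, extracellular matrix, unfolded protein response and fibroblast genes, 1, 0, 0 and 0 rose and 0 fell (2, 0, 3 and 2 up and 0 down adjusted over the list alone). The medians were 0.45, 0.20, 0.24 and 0.26, and 0.21 to 0.62, 0.05 to 0.38, 0.12 to 0.29 and 0.10 to 0.36 within slides (camera, adjusted p = 4.57e-05, 0.00444, 0.00487 and 0.00671, or adjusted p = 0.614, 0.785, 0.645 and 0.713 with an estimated correlation). Of 23, 22, 10 and 12 measured DNA replication, cholesterol synthesis, basal and myoepithelial, and endothelial genes, 0 rose and 0, 0, 0 and 1 fell (0 up and 0, 0, 0 and 1 down adjusted over the list alone). camera gave adjusted p = 0.0119, 0.0124, 0.0339 and 0.0369, or adjusted p = 0.226, 0.536, 0.480 and 0.395 with an estimated correlation, for medians of -0.23, -0.30, -0.33 and -0.37 (-0.29 to -0.24, -0.48 to 0.05, -0.59 to -0.24 and -0.43 to -0.27 within slides). limma called 121 genes higher and 30 lower. No call was made for 15 panel genes, the 11 not dim at -0.72 (Cxcl12) to 0.62 (Vim). Well above background were Nbea and Pecam1 on 1 of 3 P arrays, Serpina1d on 2; Rex1bd, Ap2s1 and Ier2 on 2 of 3 vehicle arrays. The count was 15 with slide as a block (4 of 14 named). It was 99 and 75 without vehicle arrays 2 and 3, and 19, 592 and 10 without P arrays 1 to 3.

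EP set against E in stromal cells differed in 6 genes, all higher (limma, 1010 at an unadjusted p under 0.05): the oxidase Nox4 and Cyp2f2 by 1.72 ± 0.19 and 1.44 ± 0.18 (n = 3 and 3), with C-reactive protein (Crp) and Cnga2 at least 3.96 and 3.73 fold higher among them. Not passing were 16 panel genes, the 15 not dim at -0.56 (Id4) to 0.84 (Greb1). Blocking for slide left 0 genes (0 of 4 named). Leaving out single arrays gave 3 without vehicle array 2, 17, 2 and 3 without E arrays 1 to 3, 3 without P array 2, and 0, 1 and 0 without EP arrays 1 to 3.

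EP set against P raised Ctla2a, Ngfr and Greb1 by 4.39 ± 0.22, 3.46 ± 0.31 and 2.58 ± 0.28 (n = 3 and 3), with the phosphatase Ptpn5, Akr1cl, Pgr and Rspo1 at least 9.80, 6.34, 4.53 and 3.09 fold higher. Hes2 and the growth factor binding protein Igfbp3 fell, at -2.19 ± 0.40 and -1.98 ± 0.27, and Tas2r126 and Cox8b were at least 4.40 and 3.62 fold lower. limma called 202 genes higher and 193 lower. 13 panel genes did not pass, the 12 not dim at -1.26 (Esr1) to 0.38 (Ccnd1). Measured on part of the arrays were Hes2 on 1 of 3 EP arrays; Ngfr on 1 of 3 P arrays, Greb1 on 2. 21 genes passed with slide as a block (6 of 11 named), and the split 222 and 136 with the scanner's signals and 224 and 345 with the authors' log2 values. It became 173, 239 and 151 without P arrays 1 to 3, and 101, 86 and 181 without EP arrays 1 to 3. The EP effect exceeded the sum of the E and P effects for Crp, Nox4 and Nbea, by 2.20 ± 0.23, 2.15 ± 0.26 and 2.12 ± 0.23, and lay below it for Ndufa6, by -2.82 ± 0.26, and for 1 gene with no symbol. In all 3 stromal genes lay above and 2 below additivity (limma, 1747 at an unadjusted p under 0.05). Crp was not well above background in at least 1 group. None of 16 panel genes passed, the 11 not dim with values from -0.54 (Vim) to 1.31 (Pecam1). A block for slide left 0 genes (0 of 4 named), and the split 2 and 6 with the scanner's signals and 6 and 12 with the sample channel alone. Without single arrays it was 10 without vehicle array 1, 12 and 3 without E arrays 1 and 2, 3 and 75 without P arrays 1 and 2, and 2, 2 and 1 without EP arrays 1 to 3.

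The EP effect was called different in luminal and basal cells in 1765 genes, fewer with array weights. Klk1, Thrsp and Tnxb had a luminal effect above the basal one by 5.12 ± 0.63, 4.60 ± 0.42 and 4.37 ± 0.47, and so did Krt14, Krt5, Vim, Pecam1, Cxcl12, Tnfsf11 and Greb1, by 3.19 ± 0.42, 1.75 ± 0.34, 3.18 ± 0.38, 2.78 ± 0.54, 2.30 ± 0.33, 2.15 ± 0.55 and 1.50 ± 0.47; for Pgr the difference was -1.21 ± 0.32, and its other probe had the opposite sign. Endothelial markers fell in basal cells, Pecam1 among them, as did Vim and Cxcl12. Stromal minus basal, Ctla2a and Ctla2b lay at 7.19 ± 0.76 and 4.43 ± 0.55 and Pank1 and Mycn at -4.65 ± 0.77 and -4.11 ± 0.90. Stromal minus luminal, Pnmt, Klk1, Napsa and Pcp4 lay at -4.31 ± 0.53, -4.38 ± 0.65, -4.39 ± 0.43 and -4.41 ± 0.48. limma called 906 higher and 859 lower luminal minus basal, 919 and 990 stromal minus basal, and 267 and 349 stromal minus luminal. Cxcl12, Krt5, Mycn, Napsa, Pank1, Pcp4, Pecam1, Pnmt, Thrsp, Tnfsf11 and Tnxb were not well above background in at least 1 group. Of the panel 16, 19 and 19 genes did not pass, the 10, 7 and 8 not dim from -1.58 (Ccnd1, luminal minus basal) to 1.28 (Greb1, stromal minus basal). The 3 counts with slide as a block were 1248, 1436 and 530 (9, 4 and 4 of 11, 4 and 4 named), and stromal minus luminal 1395 without the arrays in doubt. Luminal minus basal, the EP split was 801 and 1615 with the scanner's signals and 2780 and 1635 with the authors' log2 values, and the count 4276 without basal vehicle array 2, and 1078 without luminal vehicle array 2. Stromal minus basal, the EP split was 858 and 1461 with the scanner's signals, and the count 3816 without basal vehicle array 2, 1236 without stromal vehicle array 3, and 1268 without stromal EP array 2.

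For E, Aoc1 and Ctla2a had a luminal effect above the basal one by 4.00 ± 0.54 and 3.96 ± 0.73 and Kcnh1 one of -4.0 ± 0.67, with Krt14, Krt5, Pecam1, Vim and Cxcl12 at 2.40 ± 0.42, 2.13 ± 0.34, 2.00 ± 0.54, 1.70 ± 0.38 and 1.57 ± 0.33. Endothelial markers, Pecam1, Cxcl12 and Ctla2a fell in basal cells under E. Stromal minus basal, Ctla2a lay at 7.06 ± 0.76, and Lpar3, Hamp and Bglap2 at -4.35 ± 1.08, -4.22 ± 0.66 and -4.05 ± 0.54. Stromal minus luminal, Lrrn2 and Spon1 lay at 3.52 ± 0.42 and 3.26 ± 0.57, and Aoc1 and Scgb3a1 at -3.95 ± 0.56 and -3.73 ± 0.39. The counts higher and lower were 291 and 306 luminal minus basal, 427 and 423 stromal minus basal, and 57 and 86 stromal minus luminal. Aoc1, Bglap2, Hamp, Kcnh1, Krt5, Lpar3 and Lrrn2 were not well above background in at least 1 group. Of the panel 19, 23 and 21 genes did not pass, the 10, 10 and 8 not dim from -1.70 (Ccnd1, luminal minus basal) to 1.72 (Pecam1, stromal minus basal). The 3 counts with slide as a block were 686, 855 and 162 (8, 4 and 4 of 8, 4 and 4 named), and stromal minus luminal 340 without the arrays in doubt. Luminal minus basal, the E split was 307 and 707 with the scanner's signals and 1781 and 720 with the authors' log2 values, and the count 926 and 3087 without basal vehicle arrays 1 and 2, and 313 and 386 without luminal vehicle arrays 2 and 3. Stromal minus basal, the E split was 407 and 738 with the scanner's signals and 1846 and 998 with the authors' log2 values, and the count 1396 and 2716 without basal vehicle arrays 1 and 2, 493 and 477 without stromal vehicle arrays 2 and 3, and 528 and 469 without stromal E arrays 1 and 3. Stromal minus luminal, the E count was 86 and 90 without luminal vehicle arrays 2 and 3, 95 without luminal E array 4, 82 and 89 without stromal vehicle arrays 2 and 3, and 91 and 79 without stromal E arrays 2 and 3.

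For P, Ccl21b, Ccl21a and Pecam1 had a luminal effect above the basal by 3.80 ± 0.91, 3.69 ± 0.93 and 2.38 ± 0.58. All 13 endothelial markers lay lower in basal P, 0 passing. Stromal minus basal, Alkbh6, Olfr56 and Reg3d lay at 4.30 ± 0.99, 3.87 ± 0.95 and 3.83 ± 0.96 and Bglap2 at -3.98 ± 0.56. The counts were 101 higher and 126 lower luminal minus basal, 206 and 200 stromal minus basal, and 0 stromal minus luminal (limma, 1126 genes at an unadjusted p under 0.05). Alkbh6 and Bglap2 were not well above background in at least 1 group. Of the panel 23, 24 and 24 genes did not pass, the 14, 11 and 10 not dim from -1.97 (Ccnd1, stromal minus basal) to 1.13 (Krt8, luminal minus basal). The 3 counts with slide as a block were 290, 549 and 0 (0 and 3 of 3 and 4 named), and stromal minus luminal 0 without the arrays in doubt. Luminal minus basal, the P split was 620 and 302 with the authors' log2 values, 73 and 156 with scale normalization and 57 and 140 with no background correction, and the count 619 and 1849 without basal vehicle arrays 1 and 2, 86 and 149 without luminal vehicle arrays 2 and 3, and 77 without luminal P array 2. Stromal minus basal, the P split was 229 and 394 with the scanner's signals and 1224 and 455 with the authors' log2 values, and the count 918 and 2128 without basal vehicle arrays 1 and 2, 262 and 741 without basal P arrays 2 and 3, 245 and 176 without stromal vehicle arrays 2 and 3, and 151 and 137 without stromal P arrays 1 and 3. Stromal minus luminal, the P count was 2 and 2 without stromal vehicle arrays 1 and 3.

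Within a compartment E and EP shared many of their genes. Stromal cells had 101 genes higher and 10 lower under E, P and EP alike, basal cells 42 and 19, and luminal cells 0 and 1. E and EP shared 339 higher and 374 lower genes in basal cells, 236 and 166 in luminal cells and 612 and 427 in stromal cells. Independent sets would share 18.0 and 24.7, 14.9 and 11.3, and 36.2 and 30. The covariance of the E and EP effects across genes was 0.481, 0.222 and 0.255 in basal, luminal and stromal cells, against 0.106, 0.0684 and 0.0535 simulated from the common controls; for P and EP it was 0.318, 0.0807 and 0.152 against 0.108, 0.0672 and 0.0515, and for E and P 0.296, 0.0701 and 0.135 against 0.112, 0.0675 and 0.0516. The 3 vehicle arrays of a compartment cannot be split into separate controls, so part of the excess may come from shared arrays.

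Between compartments, which share no arrays, fewer genes coincided. EP changed 141 genes up and 132 down in both epithelial compartments (independent 40.7 and 39.5) and 27 in opposite directions. Luminal and stromal cells shared 219 EP genes, 112 of them lower (independent 32.7 higher and 30.7 lower, 38 opposite), and basal and stromal cells 43 and 71 (independent 36.2 and 34.7, 60 opposite). Among genes with a symbol that could be named, 7 were higher and 15 lower under EP in all 3 compartments. The 7, named after their values were seen, were Gpx3, the desaturase Scd2, Plac8, the mitochondrial enzymes Cpt2 and Fh1, Cfap410 and Spdl1. For E the numbers higher and lower were 13 and 17 in both epithelia (independent 4.58 and 4.77), 15 and 58 in basal and stromal (independent 11.7 and 16.3) and 13 and 35 in luminal and stromal cells (independent 6.98 and 7.93). Acp5 was the gene that rose under E in all 3 compartments, and P shared 0 genes between any pair.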

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

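The tests of other splits, array quality, shares of basal RNA, slide and the array with a weak reference were chosen after the result was seen.

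Endothelial markers were lower in basal arrays of hormone-treated than of vehicle mice. The array quality of vehicle replicates 1 and 3 rests on 1 array: vehicle replicate 2, of ordinary quality, lay at -0.77, above the 11 hormone arrays at -3.01 to -1.57, which leaves this open. Endothelial cells in the basal sort, more of them in vehicle mice, are a candidate source: on a second list of 26 endothelial genes, 20 of them measured, all lay lower under EP, with a median of -1.68 and 15 passing. The median was -1.58 under E, with 12 passing, and -0.96 under P, with 2 passing. Pecam1 lay at 0.01 ± 0.40 in basal vehicle cells and -2.32 ± 0.28 in luminal ones. Whether a gate removed such cells is not given in the sources used here, and fewer transcripts per endothelial cell under hormones stay open, untested.

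Krt14 and other basal genes were higher in luminal EP than luminal vehicle arrays. As the whole cause of the Krt14 rise, basal cells in the luminal sort would need 26.7% of the RNA and a median rise of 2.93 in 11 genes that basal cells hold at 16-fold or more; the rise was 1.10 (0.10 to 1.46), which argues against it. For the other genes it stays open: Serpina3n, Erc2 and Arc lay at 0.10, 0.00 and -0.14 and the others at 0.96 to 1.84, needing a median share of 3.16%, 6 within 2-fold of it (-0.445 to 41.6%). Slide is argued against, since the basal list's median was 1.27 with it as a block and 1.08 without. A change of luminal cells themselves stays open and was not tested.

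P alone changed 1 luminal gene, and P added to E 480. Over the latter the slope of the P effect without E on that with E was 0.112 (0.0849 to 0.139, 331 of the same sign, r = 0.391 across genes, which are not independent), against 1 for an equal response missed by the threshold, which argues against it. Without replicate 2, whose reference was weak, it was 0.0637 (0.0329 to 0.0949, 280 of the same sign, r = 0.215), which argues against that array as the cause. The genes were selected in EP against E, whose chance values can lower a slope. Additivity, tested over all genes, was departed from by 54, Klk1b3 by 4.51 ± 0.49 and Spp1 by -4.07 ± 0.37. Whether P needs E for other genes stays open: without passing, Tnfsf11 and Rspo1, not well above background in vehicle, and Cxcr4 lay at 1.40 ± 0.54, 1.20 ± 0.42 and 1.19 ± 0.30 under P alone, and no panel gene passed for additivity.

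Effects differed between compartments (limma's test of the difference, log2). For EP they differed luminal minus basal in 1765 genes, with Cxcl12, Greb1, Klk1, Krt14, Krt5, Pecam1, Pgr, Thrsp, Tnfsf11, Tnxb and Vim at 2.30, 1.50, 5.12, 3.19, 1.75, 2.78, -1.21, 4.60, 2.15, 4.37 and 3.18, stromal minus basal in 1909 genes, with Ctla2a, Ctla2b, Mycn and Pank1 at 7.19, 4.43, -4.11 and -4.65, and stromal minus luminal in 616 genes, with Klk1, Napsa, Pcp4 and Pnmt at -4.38, -4.39, -4.41 and -4.31. For E they differed luminal minus basal in 597 genes, with Aoc1, Ctla2a, Cxcl12, Kcnh1, Krt14, Krt5, Pecam1 and Vim at 4.00, 3.96, 1.57, -4.0, 2.40, 2.13, 2.00 and 1.70, stromal minus basal in 850 genes, with Bglap2, Ctla2a, Hamp and Lpar3 at -4.05, 7.06, -4.22 and -4.35, and stromal minus luminal in 143 genes, with Aoc1, Lrrn2, Scgb3a1 and Spon1 at -3.95, 3.52, -3.73 and 3.26. For P limma called 227 genes luminal minus basal, with Ccl21a, Ccl21b and Pecam1 at 3.69, 3.80 and 2.38, and 406 stromal minus basal, with Alkbh6, Bglap2, Olfr56 and Reg3d at 4.30, -3.98, 3.87 and 3.83. Of these Alkbh6, Aoc1, Bglap2, Cxcl12, Hamp, Kcnh1, Krt5, Lpar3, Lrrn2, Mycn, Napsa, Pank1, Pcp4, Pecam1, Pnmt, Thrsp, Tnfsf11 and Tnxb were not well above background in at least 1 group, and the other probe of Pgr had the opposite sign.

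In groups of 4, 1 array stood apart from the other 3 for 20 of 319 genes tested, 5 of 132 lists and 1 of 16 array measures; chance gives about 1 in 20. The gap, as a share of the group's range, was in basal E 0.874 for MHC class II list (high on replicate 1), 0.942, 0.883 and 0.885 for Fads1, DNA replication list and oxidative phosphorylation list (low on replicate 2), 0.885 for the median Cy5 signal (high on replicate 3), 0.831 for Cd82 (low on replicate 3), 0.884 for Fcgbp (high on replicate 4), in basal EP 0.851 and 0.876 for Krt15 and Mcm7 (low on replicate 1), 0.845 for Fads1 (high on replicate 3), 0.899, 0.858 and 0.865 for Ceacam2, Rprl2 and pericyte markers list (low on replicate 3), 0.830 for Hp (low on replicate 4), in luminal E 0.832 for Col6a1 (low on replicate 1), 0.907 and 0.859 for Cnn1 and Myl9 (high on replicate 2), 0.850 for Lama4 (low on replicate 3), 0.915 for Col1a1 (high on replicate 4), and in luminal EP 0.875 for Ceacam2 (high on replicate 3), 0.856, 0.877, 0.834, 0.946 and 0.957 for Apod, Col4a2, Ctla2a, Upf1 and Vim (high on replicate 4), 0.900 for chemokines list (low on replicate 4).

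Counts were set against other splits of the same arrays into groups of the same sizes (B, L and S: basal, luminal, stromal; EP/E: EP against E). Among 35 splits chance can be excluded, with real count and highest other of basal E 906 and 115, EP 2075 and 1, EP/E 32 and 1, EP/P 441 and 1, luminal E 559 and 2, EP 1967 and 1167, and EP/E 480 and 79. Among 100 splits drawn chance is argued against in the same way, with at most 4 as large (the real one included), for L-B 8788 and 2452, S-B 10378 and 3284, and S-L 10897 and 3190. With as few, additivity and differences stay undecided, as splits mix treatments into the spread. Additivity gave basal 7 and 9, luminal 54 and 13 and stromal 5 and 2216. Differences for E gave L-B 597 and 655, S-B 850 and 1979 and S-L 143 and 432. For EP they gave L-B 1765 and 3354, S-B 1909 and 1899 and S-L 616 and 2411. Splits with several times the real count can hold treatment or compartment effects, untested. With slide as a block basal and stromal additivity kept 0 and basal EP/E 1. Chance cannot be excluded with luminal EP/P 1424 and 2081, P L-B 227 and 1107, and P S-B 406 and 802, where 2, 32 and 8 splits were as large. P S-L, with 0 genes (highest other 215), leaves nothing to test. The highest others of luminal EP against P and of luminal EP set EP replicate 4 with the 3 P or the 3 vehicle arrays. 10 splits are too few for a share under 0.05, and gave basal P 111 and 396, luminal P 1 and 74, stromal E 1617 and 1, P 151 and 0, EP 1757 and 1, EP/E 6 and 10, and EP/P 395 and 0.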

How the results depend on the processing

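Counts without the arrays in doubt were chosen after the result was seen, all other settings before the data were examined. With the short forms above, E L-B is the luminal minus basal difference of the E effect, and L-B alone the comparison of both compartments. Over 384 counts recomputed under other settings 237 stayed within 1.5 times, and of 720 with 1 array left out 560 did. L-B, S-B and S-L kept within 1.5 times under every setting. Where a count fell or rose with fewer arrays or genes in the fit, these can be part of the cause, which was not tested.

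Without background correction the moved counts were basal additivity 3 and stromal additivity 8. The scanner's processed signals gave basal P 193, EP/E 19, additivity 64, luminal E 997, P 13, EP/P 2360, additivity 120, stromal additivity 8, E L-B 1014, E S-L 233, P L-B 366, P S-B 623 and P S-L 2. Scale normalization gave basal EP/E 14, EP/P 174, additivity 2, luminal E 262, P 0, EP/E 259, E S-L 94, P S-B 254 and P S-L 2. The sample channel alone gave basal P 202, EP/E 52, additivity 36, luminal E 1406, P 15, EP 3765, EP/E 958, EP/P 3283, additivity 235, stromal additivity 18, E L-B 1041, E S-B 1474, E S-L 384, P L-B 412, P S-B 652, P S-L 7 and EP S-L 1146. Without a filter counts were basal additivity 2, luminal E 365, stromal E 990, P 90, EP/E 3 and EP/P 237, with the stricter filter basal additivity 3 and E S-L 82, and with the mean of probes luminal P 0. Slide as a block gave basal E 426, P 48, EP 1108, EP/E 1, EP/P 120, additivity 0, luminal P 0, EP/P 136, additivity 8, stromal E 26, P 15, EP 114, EP/E 0, EP/P 21 and additivity 0. The fits over other samples gave basal E 3592, P 1807, EP 5564, EP/E 201, EP/P 2024, additivity 418, luminal P 3, additivity 102, stromal E 649, P 62, EP 809, EP/E 13, EP/P 217, additivity 1, E L-B 269, E S-B 530, E S-L 288, P L-B 71, P S-B 164, EP L-B 1019 and EP S-L 1099. Array weights gave basal E 16, P 0, EP 1.1e2 (63 up and 44 down), EP/E 481, EP/P 914, additivity 0, luminal E 1040, EP 3058, EP/E 1054, EP/P 3376, additivity 181, stromal EP 3251, EP/E 10, EP/P 1420, E L-B 57, E S-B 79, E S-L 438, P L-B 4, P S-B 6, P S-L 9, EP L-B 384, EP S-B 641 and EP S-L 2017. The authors' values gave basal E 420, EP 1280, EP/E 6, EP/P 74, additivity 11, luminal P 3, EP/P 2164, stromal E 3364, P 69, EP 2934, EP/E 12, additivity 18, E L-B 2501, E S-B 2844, P L-B 922, P S-B 1679, EP L-B 4415 and EP S-B 3486. Without the arrays in doubt together counts were basal E 233, EP 457, EP/E 112, EP/P 2166, additivity 71, luminal P 0, additivity 1.1e2 (56 up and 51 down), E S-L 340, EP L-B 896 and EP S-L 1395.

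Only 11 of 40 arrays correlated best with their own replicate number. A replicate block gave basal E 311, P 37, EP 970, EP/E 0, EP/P 61, additivity 1, luminal E 260, P 0, EP/E 313 and stromal additivity 3. Its other counts stayed within 1.5 times.

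With 1 array left out the lowest and highest counts were basal E 370 to 3480, P 56 to 2620, EP 794 to 4509, EP/E 0 to 50, EP/P 63 to 1197, additivity 1 to 919, luminal E 207 to 784, P 0 to 20, EP 1060 to 2353, EP/E 259 to 538, EP/P 772 to 2403, additivity 31 to 91, stromal E 506 to 1625, P 10 to 592, EP 519 to 1829, EP/E 0 to 17, EP/P 86 to 386, additivity 1 to 75, E L-B 313 to 3087, E S-B 469 to 2716, E S-L 79 to 198, P L-B 77 to 1849, P S-B 137 to 2128, P S-L 0 to 2, EP L-B 1078 to 4276 and EP S-B 1236 to 3816.

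Of 14060 recomputed values of named genes 12874 kept their call or lack of one, 1100 lost a call, 85 gained one and 1 turned. The direction of a gene was compared only where either fit made a call. Slide as a block alone ended the call of 120 of 383 named genes that passed, whose values stood at a median of 0.991 and errors at 1.13 times those without it. Of 7719 list tests 7366 kept both, 121 lost and 232 gained a call, and 0 turned. Sparc turned, at -0.31 in stromal EP (sample channel alone).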

Other observations

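No test was planned for the values in this part, which were chosen after the data were seen.

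Levels in vehicle arrays are mean log2 ratios to the reference ± SD (n = 3), and differences among these arrays alone were not tested. Esr1 lay at 1.05 ± 0.39 in luminal, 0.69 ± 0.42 in stromal and -1.21 ± 0.62 in basal cells.

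Arrays of 1 slide deviated from their groups together, with a mean correlation of 0.0861 over 40 pairs of 1 compartment, against -0.0213 over 160 pairs on different slides.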
